A study of Mus musculus with 16 samples.

How the data were processed

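Atrial tissue of 10-week-old male C57BL/6 mice was measured on 16 single-colour expression arrays, 4 from sham-operated mice and 4 each from mice 1, 3 and 7 days after myocardial infarction. Infarction was made by tying off the left anterior descending coronary artery. How long after surgery the sham tissue was taken is not given in the sources used here, where the series title speaks of 0 days. The labels name a 3' expression array of the mouse genome, but the names of the measured rows are those of transcript clusters and of a different set of controls, which are not probe sets of that array. The array design is therefore uncertain. Row names were joined to gene symbols through an annotation table of these transcript clusters, and the gene names of the mouse assembly GRCm38.p6 were used only to update symbols.

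The value table deposited by the authors holds log2 signals, 1 column per array and 72688 rows without missing values. The submitters' processing notes name Affymetrix Expression Console. The background correction, summarisation and scaling steps are not given in the sources used here, so differences are given as log2 differences of the deposited signal and are not turned into folds. Column medians ranged from 4.17 to 4.61, which shows that the columns were not quantile-normalised at this level. Values stop at 19.93 on all arrays except day 1 array 13, at 19.82, and day 3 array 31, at 19.80. Of the tested genes 73 have a mean above 19, and 45 of these lay at a fixed distance below the highest value of each array, with an SD of that distance under 0.05. Some of the 45, such as Gapdh with a mean of 19.33, have a plateau of their own below 19.93. No difference can be read from a gene on such a plateau. At the other end, a gene at or below the median of the negative controls on every array of a group was taken as not above background there, a rule chosen after seeing the data. Its difference is then a lower bound, written "at least" or "or more", with the mean of those medians in place of the lower group. Of the genes called against sham on days 1, 3 and 7, 664, 492 and 264 had 1 such group. In 230, 152 and 74 more both groups were such, and no size can be read from them. Ccl7, Ccr2 and Clec4d had 1 of 4 sham values there, and Ptn 1 of 4 day 3 values.

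Of the rows, 6732 were controls, 30604 carried 1 gene symbol, 2146 carried several and 33206 carried none. Rows with 1 symbol gave 30142 genes, and 22818 of those rows matched a reference gene name, 827 of them after a symbol was updated. For the 291 genes with several rows the row with the highest mean was used. A gene was tested when at least 4 of the 16 arrays lay above the median of all rows of that array, which left 18418 genes. The number of arrays limits the precision of every value.

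A linear model with 1 mean per group was fitted to each gene across all 16 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend in the variance. Each infarction day was compared with sham, and the days were compared with one another, which makes 6 pairwise comparisons. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene was called at an adjusted p under 0.05. The number of calls with an absolute log2 difference of at least 1 is given beside it, and a moderated F test over the 3 comparisons with sham tested for any difference. These p-values use the within-group spread pooled over all 16 arrays. Means are given with the SD over n = 4 arrays, and log2 differences with the SE of the fit, also at n = 4 per group.

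The grouping, the tests, 40 gene lists and the rule for naming genes were fixed in advance. The lists cover cardiomyocyte programmes, energy metabolism, immune cells and signals, stress and clock responses, matrix and its remodelling, other cell types of the heart, tissues that an atrial dissection could carry, and cell division. They hold 794 genes, of which 731 are annotated on the array. Each list with at least 5 measured members, 37 in all, was tested with camera, a competitive set test in limma, at the preset inter-gene correlation of 0.01 and again with an estimated correlation. Camera p-values were adjusted over the lists within a comparison. For each infarction day the rule names the 12 largest rises and 10 largest falls among called genes whose 4 values do not overlap those of sham, ranked by measured differences, bounds included, and passing over clone, RIKEN, predicted and expressed-sequence symbols. For comparisons between days it names 6 of each, and for each list and day the 3 called members with the largest difference, or 2 measured members where none is called. Nppa and Nppb are always named, and Actb and Gapdh serve as control genes. A planned comparison of 3' and 5' control probes could not be made, because the table holds no such controls. The separation of positive from negative control rows, as the area under the receiver operating curve (control separation, where 1 is complete), took its place and was chosen after seeing the data.

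Overlaps of calls between days were set against the product of the separate shares, 100 simulations of unchanged groups measured against the same sham arrays, and 6 comparisons in which each day had its own pair of sham arrays. Every pairwise count was recomputed for all 35 splits of its 8 arrays into groups of 4, and the F-test count for 100 drawn splits. The fit was tested on simulated data with independent noise at the day 1 comparison. It recovered 14, 35, 48 and 49 of 50 genes given log2 differences of 0.5, 1, 2 and 4, and it called 10 of 18188 unchanged genes.

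The alternatives chosen before the data were examined were quantile normalisation, centring of each array on its median, no filter, a filter on the mean, the mean of all rows of a gene, every row on its own, eBayes without trend or with robust estimation, array weights, a fit of only the 8 arrays compared, a block on the last digit of the replicate number, each array left out in turn, a minimum log2 difference of 1, and for the lists an estimated correlation. Pseudocounts did not apply to log2 values, and the planned exclusion of cross-hybridising probe sets did not apply because the row names carry no such mark. Fits without both arrays of lowest control separation, with control separation as a covariate, and without genes near the ceiling were chosen after seeing the data. Rows without a gene symbol were not used in the comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.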

Results

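The atria, the upper chambers of the heart, were measured in 16 mice. Of these 4 had sham surgery, and 4 each infarction of the left ventricle 1, 3 or 7 days earlier. As far as the labels state a purpose, it is how atrial gene expression changes in the first week after infarction. Arrays are named by group and number, sham 1 to 4, day 1 arrays 11 to 14, day 3 arrays 31 to 34 and day 7 arrays 71 to 74.

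Signal quality was not equal across arrays. Control separation was 0.812 to 0.821 in the sham arrays and 0.813 to 0.823 in the day 7 arrays. It was 0.743 in day 3 array 31 against 0.816 to 0.825 in the other day 3 arrays. Day 1 array 13 had 0.755, and the other day 1 arrays had 0.793 to 0.804. The day 1 mean was 0.787 ± 0.022 (SD, n = 4) against 0.818 ± 0.0039 in sham, with an exact two-sided permutation p of 0.0286, the smallest this design allows, and an adjusted p of 0.0858 in a family of 9 such tests. The median correlation with the other arrays of the group was 0.951 for array 31, 0.988 for array 13 and 0.994 to 0.997 for the rest. Both arrays were kept.

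**Figure D1:**
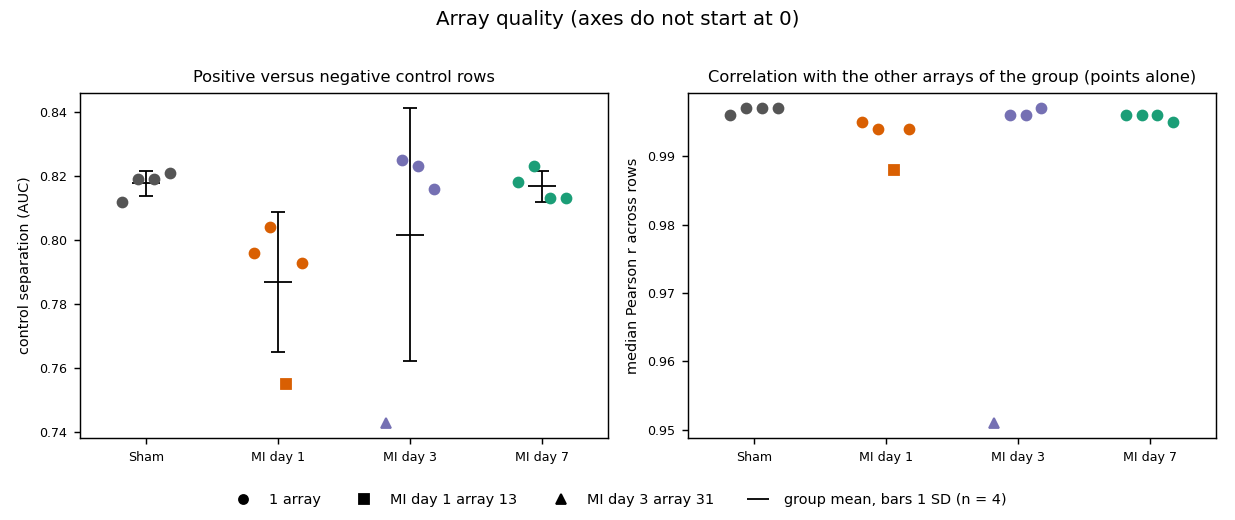
Control separation (area under the curve, no unit) and median correlation with the other arrays of the group, 1 point per array in each of the 4 groups, with the group mean and SD (n = 4) drawn for control separation alone. Day 3 array 31 is lowest in both, at 0.743 and 0.951, and day 1 array 13 next, at 0.755 and 0.988.

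One day after infarction the atria carried a strong innate immune signal and less RNA of the atrial muscle programme. Transcripts of neutrophils, the first white cells to enter injured tissue, rose. S100a8, which encodes a calcium-binding protein stored in neutrophils, stood at 12.45 ± 0.84 against 4.24 ± 0.30 in sham (SD, n = 4), a log2 difference of 8.21 ± 1.00 (SE), with 3 of 4 sham values not above the median negative control of the array. Nppb, the gene of the B-type natriuretic peptide released by stretched heart muscle, rose from 14.27 ± 0.85 to 17.66 ± 0.19, a log2 difference of 3.39 ± 0.34. Kcnj3, which encodes a subunit of the atrial acetylcholine-activated potassium channel, fell from 13.48 ± 0.33 to 8.22 ± 0.98, a log2 difference of −5.26 ± 0.94.

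Of 15 measured neutrophil genes 14 were called higher on day 1, as many when adjusted over the list alone, with a median log2 difference of 4.49. Retnlg rose by at least 8.37 and Slfn4, a gene of myeloid cells, by at least 8.34 (adjusted p 1.1e-05 and 4.2e-05), since neither was above the median negative control on any sham array. Camera gave adjusted p = 2.57e-08 for the neutrophil list, and adjusted p = 0.259 with an estimated correlation. Of 16 genes of monocytes and recruited macrophages 11 were called higher and 0 lower (11 adjusted over the list alone), led by Arg1, which encodes the arginine-degrading enzyme of alternatively activated macrophages, at 8.51 ± 0.66. Ccr1, a chemokine receptor, rose by 5.31 ± 0.27. Camera gave this list an adjusted p of 3.09e-06, and adjusted p = 0.243 with an estimated correlation. Of 19 general macrophage genes 12 were called higher (13 adjusted over the list alone), among them the integrin gene Itgam at 6.25 ± 0.47 and the lysosomal protease gene Ctss, at 14.59 ± 0.34 against 9.59 ± 0.23. Their camera adjusted p was 1.24e-05, and adjusted p = 0.343 with an estimated correlation. Of 12 resident macrophage genes 3 were called higher and 3 lower (4 and 3 adjusted over the list alone), and their median of −0.23 and mean of 0.15 differ in sign (camera adjusted p 0.86).

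Chemokine and cytokine genes rose with the cell markers on day 1, 14 of 21 called higher and 0 lower (15 higher adjusted over the list alone). The neutrophil attractant Cxcl2 rose by at least 5.43, the monocyte attractant Ccl2 by 4.49 ± 0.42, and Il1b, the gene of the inflammatory cytokine interleukin 1 beta, by 5.90 ± 0.69, from 4.79 ± 0.19 to 10.69 ± 1.52. Camera gave chemokine genes an adjusted p of 7.82e-07, and adjusted p = 0.186 with an estimated correlation. Of 15 genes of the inflammasome and innate sensing 9 were called higher (10 adjusted over the list alone), including Nlrp3, which encodes a sensor protein, at 1.10 or more (camera adjusted p 0.000174, and adjusted p = 0.186 with an estimated correlation). Of 21 genes of acute stress transcription 14 were called higher and 0 lower (14 and 1 adjusted over the list alone), including Ier3 at 3.07 ± 0.48 (camera adjusted p 0.000174, and adjusted p = 0.286 with an estimated correlation). Of 19 genes of oxidative stress 9 were called higher and 3 lower (10 and 4 adjusted over the list alone), led by the haem-degrading enzyme gene Hmox1 at 5.49 ± 0.40. That list had a camera adjusted p that was 0.0339, became 0.0797 without day 3 array 31 and 0.0751 without array 12, and was adjusted p = 0.286 with an estimated correlation. Of 23 interferon response genes 1 was called higher, and 0 were called when adjusted over the list alone (camera adjusted p 0.16). Of 7 lymphocyte genes 1 was called lower, as adjusted over the list alone, with a median of 0.04 and a downward camera test (adjusted p 0.786).

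The atrial muscle programme was lower on day 1. In whole tissue a changed cell mix cannot be told from lower expression per cell, here and below. Of 14 atrial cardiomyocyte genes 10 were called lower and 0 higher, as many adjusted over the list alone, with a median log2 difference of −1.21. The atrial score was −2.43 in array 12 and −1.52 to −1.47 in the other day 1 arrays. Sln, which encodes the atrial calcium-pump inhibitor sarcolipin, fell by 5.09 ± 1.29 (adjusted p 0.006), from 17.97 ± 0.19 to 12.88 ± 1.96, with 10.01 in array 12. Dkk3, which encodes a secreted Wnt modulator, was −3.13 ± 0.45. In the set test the adjusted p was 0.000174, and adjusted p = 0.343 with an estimated correlation. Of 31 ion channel genes 24 were called lower and 3 higher (24 and 4 adjusted over the list alone). Besides Kcnj3, Kcnk3, a background potassium channel gene of atrial cells, was −2.76 ± 0.38. Kcnip2, the gene of a partner of the transient outward potassium channel, was −2.64 ± 0.34. The list had camera adjusted p = 1.38e-07, and adjusted p = 0.186 with an estimated correlation. Of 20 calcium handling genes 8 were called lower and 0 higher, as many adjusted over the list alone, and 16 lower without day 3 array 31, such as Hrc at −1.90 ± 0.41, whose product binds calcium in the sarcoplasmic reticulum (camera adjusted p 0.000392, and adjusted p = 0.508 with an estimated correlation). The calcium handling score was −1.37 in array 13 and −0.82 to −0.71 in the other day 1 arrays. Of 20 sarcomere genes 9 were called lower and 1 higher, as many adjusted over the list alone, with Tcap, a gene of the Z-disc, at −3.46 ± 0.56 (camera adjusted p 0.00676, and adjusted p = 0.573 with an estimated correlation). Of 6 ventricular cardiomyocyte genes 5 were called lower (6 adjusted over the list alone; camera adjusted p 0.00354, and adjusted p = 0.336 with an estimated correlation). Of 16 genes of gap junctions and intercalated discs 3 were called higher and 5 lower, as many adjusted over the list alone (camera adjusted p 0.157).

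Day 1 array 13, with the lowest control separation of its group, had the lowest day 1 score for oxidative phosphorylation, −1.71 against −1.06 to −0.52 in the other day 1 arrays. Of 42 oxidative phosphorylation genes 31 were called lower and 0 higher (36 lower adjusted over the list alone), with a median of −0.92 and with Ndufa8, a subunit gene of respiratory complex I, at −2.11 ± 0.47. The camera adjusted p was 8.07e-08, and adjusted p = 0.508 with an estimated correlation. Of 23 genes of the citric acid cycle 18 were called lower (22 adjusted over the list alone), with Sdhc, a subunit gene of succinate dehydrogenase, at −1.59 ± 0.44 (camera adjusted p 1.24e-05, and adjusted p = 0.508 with an estimated correlation). Of 26 fatty acid oxidation genes 16 were called lower (19 adjusted over the list alone; camera adjusted p 3.19e-05, and adjusted p = 0.544 with an estimated correlation). Ppargc1a, the coactivator that drives mitochondrial genes, was −2.63 ± 0.63, and Cpt2, which encodes an enzyme of fatty acid import into mitochondria, was −2.49 ± 0.60. Of 19 glycolysis genes 8 were called higher and 6 lower (8 and 7 adjusted over the list alone), a balance that turned to 4 higher and 8 lower under quantile normalisation (camera adjusted p 0.668). The glucose transporter genes Slc2a1 and Slc2a4 were 3.44 ± 0.53 and −3.17 ± 0.61. Wall stress and fetal genes were called higher for 7 of 14 members and lower for 3 (9 and 3 adjusted over the list alone), among them Xirp1, which encodes a protein of the intercalated disc, at 3.10 ± 0.34. This list had a camera adjusted p that was 0.0321, became 0.087 without day 3 array 31, and was adjusted p = 0.508 with an estimated correlation.

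Matrix genes were not called as a group on day 1. Of 41 matrix genes 9 were called higher and 7 lower, as many adjusted over the list alone, a balance that turned to 7 higher and 8 lower under quantile normalisation (camera adjusted p 0.477). Those that rose include Thbs1, which encodes an adhesive protein of early wounds, at 8.17 ± 0.44, Fn1, the fibronectin gene, at 4.91 ± 0.44, and Tnc, the tenascin C gene, at 4.18 ± 0.47. Of 13 resident fibroblast genes 10 were called lower and 0 higher, as many adjusted over the list alone, with a median of −0.93. Dpt, the gene of dermatopontin, was −2.24 ± 0.49 and Fbln1, the gene of fibulin 1, was −1.92 ± 0.19. Camera gave this list an adjusted p of 8.27e-05, and adjusted p = 0.336 with an estimated correlation. Of 29 profibrotic genes 16 were called higher and 2 lower, as many adjusted over the list alone, with Timp1, a metalloproteinase inhibitor gene, at 4.67 ± 0.40 and Ccn2, the connective tissue growth factor gene, at 4.00 ± 0.41 (camera adjusted p 0.000392, and adjusted p = 0.432 with an estimated correlation). Of 32 genes of proteases and their inhibitors 21 were called higher and 4 lower (22 and 4 adjusted over the list alone), with Mmp8, the neutrophil collagenase gene, at 4.25 or more (camera adjusted p 1.66e-05, and adjusted p = 0.259 with an estimated correlation).

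Markers of other cell types were mostly lower or not called on day 1. Of 17 endothelial genes 2 were called higher and 4 lower, as many adjusted over the list alone (camera adjusted p 0.144), with Tek, an endothelial receptor gene, at −1.53 ± 0.28. Of 13 smooth muscle and pericyte genes 1 was called higher and 5 lower, as many adjusted over the list alone (camera adjusted p 0.0731, but 0.0395 without array 14 and 0.0498 without array 11, and adjusted p = 0.566 with an estimated correlation over all arrays), with Abcc9, a gene of the potassium channel of mural cells and muscle, at −2.47 ± 0.43. Of 15 mesothelial genes 1 was called higher and 4 lower, as many adjusted over the list alone (camera adjusted p 0.204, but 0.0311 without arrays 31 and 13, and then adjusted p = 0.547 with an estimated correlation), and the higher one was Aldh1a2, which encodes an enzyme of retinoic acid synthesis, at 2.75 ± 0.27. Of 7 Schwann cell and nerve genes 2 were called lower, as adjusted over the list alone, or 2 higher and 3 lower without array 31, with a score of −0.58 in array 13 (others −0.46 to −0.44) (camera adjusted p 0.151), and of 7 adipocyte genes 2 were called lower and 0 were called when adjusted over the list alone (camera adjusted p 0.179). Of 5 sinoatrial node genes 4 were called lower, as adjusted over the list alone, with Igfbp5 at −4.01 ± 0.53 (camera adjusted p 0.0109, and adjusted p = 0.286 with an estimated correlation). Of 32 cell cycle genes 5 were called higher and 1 lower (3 and 1 adjusted over the list alone), against 1 and 1 under quantile normalisation and 14 and 1 without array 31 (camera adjusted p 0.366). Limma called 0 of 6 skeletal muscle genes, with 2 lower at an unadjusted p under 0.05 (camera adjusted p 0.468).

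Limma called 8678 of 18418 genes on day 1 (47.1%), 4594 higher and 4084 lower, and 2874 with an absolute log2 difference of at least 1. The 4 values did not overlap those of sham for 10134 tested genes, and 7960 of these were called. Chance gives 2.86% or 526 if no shift in background sets the groups apart, as it did on day 1. The share of higher genes among the calls was 52.9% as deposited, 30.3% under quantile normalisation and 38.5% after centring each array, and quantile normalisation moved the median over all genes from 0.064 to −0.149. Camera called 22 of 37 lists at the preset correlation and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. Nppa, the gene of the atrial natriuretic peptide, was at the ceiling of the scale and the control gene Gapdh on a plateau near 19.33, so no difference can be read from either, and the control gene Actb was called higher at 1.98 ± 0.19.

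By day 3 a macrophage and cell division programme stood beside the earlier inflammation, and matrix genes were higher. Mki67, a marker of dividing cells, rose from 5.32 ± 0.19 to 11.22 ± 1.57 (SD, n = 4), a log2 difference of 5.90 ± 0.53 (SE). The macrophage gene Mpeg1, which encodes a pore-forming protein, rose from 5.66 ± 0.24 to 11.28 ± 0.67, a difference of 5.62 ± 0.41. Muscle and mitochondrial genes stayed below sham, with Hrc at 10.23 ± 0.84 against 13.35 ± 0.16, a difference of −3.12 ± 0.41. Day 3 array 31 stood apart from the other day 3 arrays in many of these groups.

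Of 32 cell cycle genes all 32 were called higher on day 3, as many adjusted over the list alone, with a median of 1.91. Top2a, which encodes an enzyme that untangles replicated DNA, rose by 4.19 ± 0.39 and Kif11, a spindle motor gene, by 3.99 ± 0.43. In the set test the adjusted p was 1.78e-15, and adjusted p = 0.381 with an estimated correlation. The mean list score of array 31 was 1.04 against 2.52 to 2.64 in the other arrays. Of 19 macrophage genes 19 were called higher, as many adjusted over the list alone, with Ctss at 6.12 ± 0.40 and Itgam at 5.11. For the macrophage list the camera adjusted p was 1.53e-09, and adjusted p = 0.269 with an estimated correlation. Of 16 monocyte and recruited macrophage genes 14 were called higher (15 adjusted over the list alone), with Arg1 at 7.01 ± 0.66 and Ccr2, the monocyte homing receptor gene, at 4.38 ± 0.32 (camera adjusted p 3.79e-07, and adjusted p = 0.158 with an estimated correlation). Of 15 neutrophil genes 13 were called higher, as many adjusted over the list alone, with S100a8 at 5.04 ± 1.00 and a wide spread of 9.28 ± 2.91 (camera adjusted p 0.000268, and adjusted p = 0.387 with an estimated correlation). The neutrophil score was 4.65 in array 31 and 1.61 to 2.08 in the other day 3 arrays.

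Of 21 chemokine and cytokine genes 17 were called higher on day 3, as many adjusted over the list alone, with the monocyte attractants Ccl12 at 4.65 ± 0.60 and Ccl7 at 4.47 ± 0.42 (camera adjusted p 8.07e-06, and adjusted p = 0.174 with an estimated correlation). Of 15 inflammasome and sensing genes 13 were called higher and 1 lower, as many adjusted over the list alone, with Il1b at 3.83 ± 0.69 (camera adjusted p 0.00156, and adjusted p = 0.158 with an estimated correlation). Of 21 acute stress genes 11 were called higher and 1 lower (12 and 1 adjusted over the list alone), with the growth regulator Myc among them at 1.29 (camera adjusted p 0.00922, and adjusted p = 0.387 with an estimated correlation). Interferon response genes were uneven between mice, with scores of 0.12 and 0.26 in arrays 31 and 32 and of 3.31 and 2.71 in arrays 33 and 34. Of 23 such genes 9 were called higher (8 adjusted over the list alone), and 21 without array 31, with Oas1a, a sensor of viral RNA, at 2.09 ± 0.62. Their camera adjusted p of 0.00581 became 0.0591 without array 33 and was adjusted p = 0.605 with an estimated correlation. Of 19 oxidative stress genes 9 were called higher and 3 lower, as many adjusted over the list alone (camera adjusted p 0.16). Of 12 resident macrophage genes 2 were called higher and 3 lower (camera adjusted p 0.405) and of 7 lymphocyte genes 2 were called lower, with a median of 0.01 and a downward camera test (adjusted p 0.568), both as adjusted over the list alone.

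Matrix genes rose as a group on day 3, 29 of 41 called higher and 2 lower (30 and 2 adjusted over the list alone), with a median of 1.41. Fn1 rose by 6.09 ± 0.44, from 8.61 ± 0.12 to 14.70 ± 0.41, and Tnc by 6.58 ± 0.47. For the list as a whole the camera adjusted p was 1.44e-07, and adjusted p = 0.387 with an estimated correlation, and the score of array 31 was 0.88 against 2.08 to 2.20. Of 29 profibrotic genes 21 were called higher and 2 lower, as many adjusted over the list alone, with Timp1 at 4.99 ± 0.40 and a score of 0.74 in array 31 against 1.33 to 1.42 (camera adjusted p 3.37e-06, and adjusted p = 0.381 with an estimated correlation). Of 32 protease genes 27 were called higher and 1 lower (27 and 2 adjusted over the list alone; camera adjusted p 4.87e-08, and adjusted p = 0.158 with an estimated correlation). Of 13 resident fibroblast genes 1 was called higher and 6 lower, as many adjusted over the list alone, with Col15a1, a basement membrane collagen gene, at 1.39 ± 0.28 and the actin-severing gene Gsn at −1.99 ± 0.27. Their camera adjusted p of 0.0228 became 0.158 without array 31, whose score was −1.14 against −0.07 to 0.06, and was adjusted p = 0.484 with an estimated correlation.

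Energy genes were lowest in array 31 on day 3, where the oxidative phosphorylation score was −2.57 against −1 to −0.79 in the other arrays. Of 42 oxidative phosphorylation genes 41 were called lower, as many adjusted over the list alone, with a median of −1.26, and 37 were called without array 31, with a median of −0.87. Of 23 citric acid cycle genes 23 were called lower, as many adjusted over the list alone, with a median of −1.60 that was −1.02 without array 31, whose score was −2.84 against −1.08 to −0.99. Of 26 fatty acid oxidation genes 23 were called lower, as many adjusted over the list alone, with a median of −1.63 that was −1.07 without array 31, whose score was −3.26 against −1.22 to −1.05. Acot2, a mitochondrial thioesterase gene, was −3.40 ± 0.61 and Ndufa8 −2.58 ± 0.47. Camera gave 2.56e-12, 2.18e-08 and 4.87e-08 in turn as adjusted p for these 3 lists, and adjusted p = 0.387 with an estimated correlation for each. Of 19 glycolysis genes 8 were called higher and 6 lower, as many adjusted over the list alone, against 5 and 7 under quantile normalisation and 7 and 8 after centring (camera adjusted p 0.858).

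Of 14 atrial cardiomyocyte genes 11 were called lower on day 3 (12 adjusted over the list alone), with a median of −1.29 that was −0.73 without array 31, whose score was −3.25 against −1.21 to −0.96. Kcnj3 was −4.19 ± 0.94. Atrial genes had a camera adjusted p of 7.31e-05, and adjusted p = 0.387 with an estimated correlation. Of 31 ion channel genes 25 were called lower and 3 higher, as many adjusted over the list alone, with Kcnk3 at −2.51 ± 0.38, Abcc9 at −2.91 ± 0.43 and a score of −1.45 in array 31 against −0.79 to −0.72 (camera adjusted p 5.43e-08, and adjusted p = 0.158 with an estimated correlation). Of 20 calcium handling genes 12 were called lower, with a score of −2.29 in array 31 against −0.76 to −0.69 (13 adjusted over the list alone; camera adjusted p 2.46e-05, and adjusted p = 0.387 with an estimated correlation). Of 20 sarcomere genes 10 were called lower, as many adjusted over the list alone, with a median of −1.02 that was −0.55 without array 31, whose score was −2.62 against −0.65 to −0.56, and with Tcap at −4.20 ± 0.56 (camera adjusted p 0.000329, and adjusted p = 0.433 with an estimated correlation). Of 6 ventricular genes 5 were called lower, as many adjusted over the list alone (camera adjusted p 0.002, and adjusted p = 0.381 with an estimated correlation). Of 16 gap junction and disc genes 1 was called higher and 7 lower, as many adjusted over the list alone, with a score of −1.43 in array 31 against −0.51 to −0.43 (camera adjusted p 0.00571, and adjusted p = 0.455 with an estimated correlation). Of 14 wall stress genes 6 were called higher and 2 lower, as many adjusted over the list alone, against 5 and 5 after centring (camera adjusted p 0.26), with Nppb at 3.35 ± 0.34.

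Among other cell types on day 3, 5 endothelial genes of 17 were called higher and 3 lower, as many adjusted over the list alone, against 1 and 4 under quantile normalisation and 3 and 4 after centring (camera adjusted p 0.985). Smooth muscle and pericyte genes were called lower for 4 of 13 members, as adjusted over the list alone (camera adjusted p 0.0921, but 0.0406 without array 34, and adjusted p = 0.528 with an estimated correlation over all arrays). Of 15 mesothelial genes 2 were called higher, as adjusted over the list alone, or 7 without array 31, and the score of array 31 was −0.74 against 0.45 to 1. Camera gave this list an adjusted p of 0.519, but 0.0482 without array 31 and 0.0279 without arrays 31 and 13, the last with adjusted p = 0.473 with an estimated correlation. Of 5 sinoatrial node genes 4 were called lower, as adjusted over the list alone. Their camera adjusted p, 0.0396, became 0.0979 without array 31 and was adjusted p = 0.387 with an estimated correlation. Of 7 adipocyte genes 1 was called lower and 0 were called when adjusted over the list alone (camera adjusted p 0.193). Of 7 Schwann cell and nerve genes 1 was called higher and 2 lower (camera adjusted p 0.26), and of 6 skeletal muscle genes 1 was called higher and 3 lower (camera adjusted p 0.166), both as adjusted over the list alone. The skeletal muscle median of −0.15 and mean of 0.06 differ in sign.

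Limma called 8049 of 18418 genes on day 3 (43.7%), 4330 higher and 3719 lower, and 2847 with an absolute log2 difference of at least 1. The groups did not overlap for 7883 genes, against 526 by chance, and 7117 of these were called. Higher genes made up 53.8% of the calls as deposited, 36.1% under quantile normalisation, which moved the median over all genes from 0.082 to −0.067, and 36.9% after centring, which moved it to −0.049. Camera called 24 of 37 lists at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05.

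By day 7 the atria carried a matrix and macrophage programme, with interferon response genes higher and neutrophil genes near sham. Postn, the gene of periostin, a matrix protein of activated fibroblasts, stood at 18.84 ± 0.16 against 11.97 ± 0.45 (SD, n = 4), a log2 difference of 6.87 ± 0.67 (SE). Col1a1, which encodes a chain of type I collagen, rose from 6.92 ± 0.22 to 13.65 ± 0.80, a difference of 6.73 ± 0.56. The secreted growth factor gene Ptn rose from 5.16 ± 0.10 to 10.50 ± 0.38, a difference of 5.34 ± 0.20. Nppb stayed above sham at 2.05 ± 0.34.

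Of 41 matrix genes 39 were called higher and 0 lower on day 7, as many adjusted over the list alone, with a median of 2.80. Fn1 rose by 7.18 ± 0.44, Col3a1, which encodes type III collagen, by 6.54 ± 0.47, and Lox, the gene of the collagen cross-linking enzyme, by 6.15 ± 0.49. The camera adjusted p was 2.91e-36, and adjusted p = 0.102 with an estimated correlation. Of 29 profibrotic genes 24 were called higher and 2 lower, as many adjusted over the list alone, with Ddah1 at 4.64 ± 0.45 and Tgfb3 at 3.13 ± 0.62. Their camera adjusted p was 9.58e-14, and adjusted p = 0.102 with an estimated correlation. Of 32 protease genes 23 were called higher and 1 lower (25 and 1 adjusted over the list alone), with the membrane-bound collagenase gene Mmp14 at 3.72 ± 0.30 (camera adjusted p 5.62e-12, and adjusted p = 0.102 with an estimated correlation). Of 13 resident fibroblast genes 7 were called higher and 3 lower, as many adjusted over the list alone, with Mfap5 at 3.21 ± 0.63 and Lum, the gene of the collagen-binding protein lumican, at 2.76 ± 0.32 (camera adjusted p 0.0321, and adjusted p = 0.599 with an estimated correlation).

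Of 19 macrophage genes 19 were called higher on day 7, as many adjusted over the list alone, with Ctss at 6.20 ± 0.40 and Mpeg1 at 5.41 ± 0.41 (camera adjusted p 2.23e-17, and adjusted p = 0.102 with an estimated correlation). Of 16 monocyte genes 12 were called higher, as many adjusted over the list alone (camera adjusted p 5.54e-08, and adjusted p = 0.102 with an estimated correlation). Of 23 interferon response genes 20 were called higher (23 adjusted over the list alone), with Ifit1, which encodes a protein that binds viral RNA, at 4.77 ± 1.15, Bst2, which encodes a tether of budding virus, at 4.77 ± 0.95 and Usp18, a brake on interferon signalling, at 4.16 ± 0.96. Camera gave this list an adjusted p of 3.88e-09, and adjusted p = 0.463 with an estimated correlation, and the day 7 scores ranged from 1.76 to 3.85. Of 32 cell cycle genes 30 were called higher (31 adjusted over the list alone), with Mki67 at 5.15 ± 0.53 (camera adjusted p 4.24e-16, and adjusted p = 0.324 with an estimated correlation). Of 21 chemokine genes 6 were called higher (8 adjusted over the list alone), including Ccl12 at 3.70 ± 0.60 (camera adjusted p 0.00171, and adjusted p = 0.324 with an estimated correlation). Of 15 inflammasome genes 6 were called higher (9 adjusted over the list alone; camera adjusted p 0.000435, and adjusted p = 0.102 with an estimated correlation). Of 15 neutrophil genes 1 was called higher, as adjusted over the list alone, the lectin receptor gene Clec4d at 1.88 ± 0.31, and the score of array 74 was 0.66 against 0.36 to 0.39 (camera adjusted p 0.365). Of 12 resident macrophage genes 1 was called higher and 4 lower, with a median of −0.21 and a mean of 0.14 (camera adjusted p 0.341), of 7 lymphocyte genes 2 higher and 1 lower (camera adjusted p 0.472), and of 19 oxidative stress genes 8 higher and 4 lower (camera adjusted p 0.147), in each case as adjusted over the list alone. After centring, 2 lymphocyte genes were called higher and 2 lower. Of 21 acute stress genes 5 were called higher, as adjusted over the list alone (camera adjusted p 0.0965, but 0.0136 without sham 4, and adjusted p = 0.599 with an estimated correlation over all arrays).

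Muscle and energy genes that were called on day 7 were mostly lower. Of 31 ion channel genes 16 were called lower and 2 higher (18 and 3 adjusted over the list alone), with Kcnk3 at −1.87 ± 0.38 and Kcnip2 at −1.68 ± 0.34 (camera adjusted p 4.96e-06, and adjusted p = 0.134 with an estimated correlation). Of 42 oxidative phosphorylation genes 10 were called lower, as many adjusted over the list alone, with Cox6a2, a muscle subunit gene of cytochrome oxidase, at −1.64 ± 0.28, and 31 were called without day 3 array 31 (camera adjusted p 1.75e-07). Of 26 fatty acid oxidation genes 5 were called lower, as many adjusted over the list alone, with Ppara, the nuclear receptor gene that governs fat oxidation, at −1.66 ± 0.22, and 21 were called without array 31 (camera adjusted p 7.5e-05). Of 23 citric acid cycle genes 2 were called lower, as many adjusted over the list alone, and 21 without array 31 (camera adjusted p 8.41e-05). All 3 energy lists had adjusted p = 0.599 with an estimated correlation. Of 14 atrial genes 1 was called lower, as adjusted over the list alone, and 6 without array 31, the called one being Stard10 at −1.53 ± 0.27 (camera adjusted p 0.0182, and adjusted p = 0.599 with an estimated correlation). Of 20 calcium handling genes 6 were called lower and 1 higher, as many adjusted over the list alone (camera adjusted p 0.0103, and adjusted p = 0.599 with an estimated correlation). Of 20 sarcomere genes 1 was called higher and 2 lower (0 and 1 adjusted over the list alone), with 1 and 8 called without array 31. The camera adjusted p of the sarcomere list, 0.0398, became 0.0606 without day 7 array 74 and 0.0519 without sham 2, and was adjusted p = 0.669 with an estimated correlation. Of 6 ventricular genes 2 were called lower, as adjusted over the list alone, and their camera adjusted p, also 0.0398, became 0.0601 without array 73 and 0.0537 without array 74, and was adjusted p = 0.587 with an estimated correlation. Of 14 wall stress genes 4 were called higher, of 16 gap junction and disc genes 1 was called lower, and of 19 glycolysis genes 1 was called lower (camera adjusted p 0.452), in each case as adjusted over the list alone. The wall stress list had a camera adjusted p of 0.096, but 0.0197 without sham 1 and 0.0228 without array 74, and adjusted p = 0.599 with an estimated correlation over all arrays. Without day 3 array 31 the gap junction list had 2 genes called higher and 5 lower, and glycolysis 4 lower. The gap junction list had a camera adjusted p of 0.0645, but 0.0309 without day 3 array 31, 0.0351 without array 72, 0.0386 without array 71 and 0.0424 without sham 1. Without arrays 31 and 13 it had 0.0102, and then adjusted p = 0.319 with an estimated correlation.

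Genes of vessel walls were partly higher on day 7. Of 13 smooth muscle and pericyte genes 6 were called higher and 1 lower (6 and 2 adjusted over the list alone), with Tagln, a smooth muscle cytoskeleton gene, at 2.52 ± 0.49 and Cnn1 at 1.71 ± 0.43 (camera adjusted p 0.0663, but 0.033 without array 73, and adjusted p = 0.599 with an estimated correlation over all arrays). Of 17 endothelial genes 3 were called higher, as adjusted over the list alone (5, with 1 lower, without day 3 array 31), including Aplnr, the apelin receptor gene, at 1.66 ± 0.27 (camera adjusted p 0.0657, but 0.0329 without array 73, 0.0378 without sham 3 and 0.0412 without array 74, and adjusted p = 0.599 with an estimated correlation over all arrays). Of 15 mesothelial genes 3 were called higher, as adjusted over the list alone (camera adjusted p 0.111, but 0.0488 without array 74, and adjusted p = 0.7 with an estimated correlation over all arrays). Of 7 adipocyte genes 1 was called higher, with a median of 0.01 and a mean of −0.02 (camera adjusted p 0.993), and of 5 sinoatrial node genes 1 was called higher (camera adjusted p 0.972), each as adjusted over the list alone. Of 7 Schwann cell and nerve genes 1 was called higher and 2 lower (1 and 4 adjusted over the list alone; camera adjusted p 0.163), and of 6 skeletal muscle genes 1 was called higher and 0 were called when adjusted over the list alone, with a median of −0.05 and a mean of 0.07 (camera adjusted p 0.577).

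Limma called 4568 of 18418 genes on day 7 (24.8%), 2741 higher and 1827 lower, and 1257 with an absolute log2 difference of at least 1. The groups did not overlap for 7049 genes, against 526 by chance, and 4274 of these were called. Leaving out both arrays of lowest control separation, neither of them in the groups compared, raised the count to 7479, and a fit of only the 8 arrays compared called 7121. Both keep the differences as they are and change only the pooled spread behind the p-values. Higher genes made up 60% of the calls as deposited and 37.9% after centring, which moved the median over all genes from −0.006 to −0.11. Camera called 20 of 37 lists at the preset correlation and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05.

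**Figure D2:**
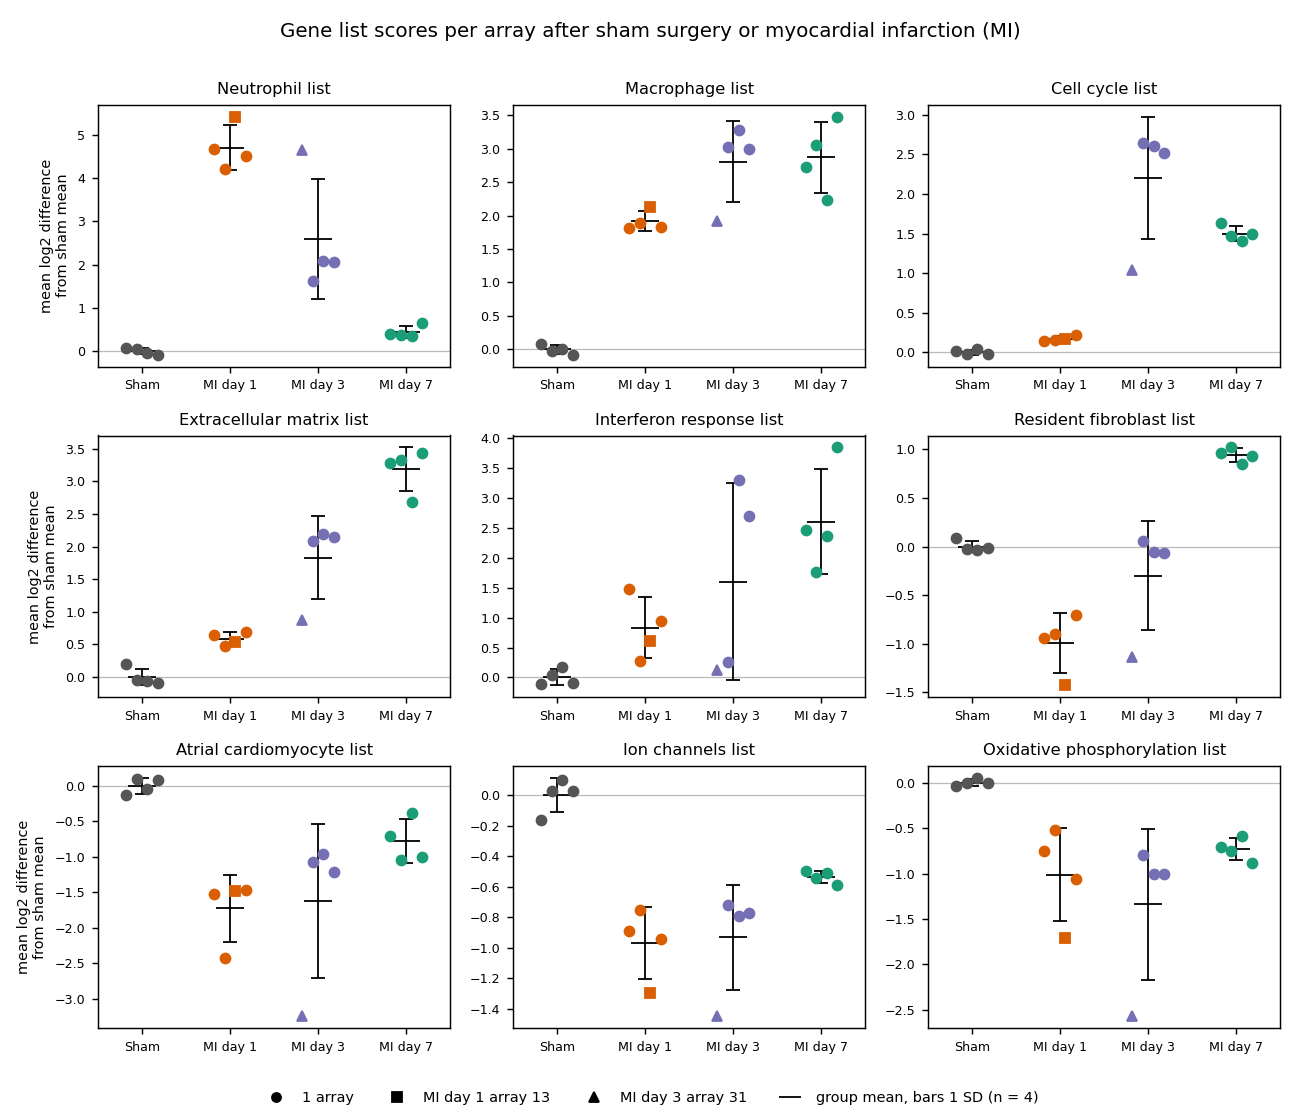
Mean log2 difference from the sham mean of the genes of 9 lists, 1 point per array in each of the 4 groups, with the group mean and SD (n = 4), day 1 array 13 drawn as a square and day 3 array 31 as a triangle. The neutrophil score of array 31 is 4.65 and its oxidative phosphorylation score −2.57.

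Between day 1 and day 3 neutrophil genes fell and cell cycle and matrix genes rose. Mki67 rose by 5.67 ± 0.53, Top2a by 3.89 ± 0.39 and Col3a1 by 3.85 ± 0.47 (SE, n = 4 per group). Retnlg was −6.12 ± 0.94 and Mmp8 −2.69 ± 0.38. Of 32 cell cycle genes 32 were called higher, as many adjusted over the list alone (camera adjusted p 2.89e-41, and adjusted p = 0.28 with an estimated correlation), and of 41 matrix genes 26 were called higher and 1 lower (29 and 1 adjusted over the list alone; camera adjusted p 1.16e-17, and adjusted p = 0.375 with an estimated correlation). Of 15 neutrophil genes 9 were called lower (12 adjusted over the list alone; camera adjusted p 1.18e-11, and adjusted p = 0.323 with an estimated correlation), and 14 without array 31. Of 19 macrophage genes 5 were called higher (13, with 1 lower, adjusted over the list alone; camera adjusted p 3.8e-05, and adjusted p = 0.61 with an estimated correlation), and 15 without array 31. Of 13 resident fibroblast genes 6 were called higher (6, with 1 lower, adjusted over the list alone; camera adjusted p 0.00494, and adjusted p = 0.61 with an estimated correlation), and 9 without array 31. Limma called 0 of 42 oxidative phosphorylation, 0 of 23 citric acid cycle and 0 of 26 fatty acid oxidation genes, with 1, 2 and 1 lower at an unadjusted p under 0.05. Their medians of −0.30, −0.37 and −0.45 turned to 0.04, 0.08 and 0.08 without array 31, and the camera adjusted p of the oxidative phosphorylation list went from 0.000645 to 0.922, and to 0.0762 without array 12 (adjusted p = 0.736 with an estimated correlation).

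Limma called 1494 genes between day 1 and day 3 (8.1%), 1096 higher and 398 lower, and 426 with an absolute log2 difference of at least 1. The groups did not overlap for 1915 genes, against 526 by chance, and 1176 of these were called. The count was 6544 without array 31, 807 without array 11, 811 without array 32, 841 without array 33 and 909 without array 34, and a fit of only the 8 arrays compared called 254, with Retnlg and Mmp8 no longer among them. Without array 31 the share of higher genes went from 73.4% to 52.8%. Camera called 15 lists at the preset correlation, 9 without array 31, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05.

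Between day 3 and day 7 matrix and fibroblast genes rose further, while neutrophil genes fell. Ptn rose by 4.96 ± 0.20, C1qtnf3, which encodes a secreted relative of complement C1q, by at least 3.90, and Thbs2, a matrix glycoprotein gene, by 3.77 ± 0.40 (SE, n = 4 per group). Arg1 was −5.63 ± 0.66, Ccl7 −3.59 ± 0.42 and Hmox1 −3.28 ± 0.40. Of 41 matrix genes 28 were called higher (34, with 1 lower, adjusted over the list alone; camera adjusted p 2.36e-23), of 13 resident fibroblast genes 11 were called higher (12, with 1 lower, adjusted over the list alone; camera adjusted p 8.34e-10), and of 13 smooth muscle and pericyte genes 7 were called higher (12 adjusted over the list alone; camera adjusted p 1.29e-07), or 4 without array 31. Each of these 3 lists had adjusted p = 0.199 with an estimated correlation. Of 15 neutrophil genes 10 were called lower (13 adjusted over the list alone; camera adjusted p 2.94e-06, and adjusted p = 0.407 with an estimated correlation). Of 21 chemokine genes 11 were called lower and 3 higher, as many adjusted over the list alone (camera adjusted p 0.000642, and adjusted p = 0.352 with an estimated correlation). Of 32 cell cycle genes 12 were called lower (18 adjusted over the list alone; camera adjusted p 3.05e-08, and adjusted p = 0.462 with an estimated correlation), and 31 without array 31. Limma called 0 of 42 oxidative phosphorylation genes, with 5 higher at an unadjusted p under 0.05, and their median of 0.57 was 0.18 without array 31 (camera adjusted p 6.55e-08, and adjusted p = 0.485 with an estimated correlation).

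Limma called 2327 genes between day 3 and day 7 (12.6%), 748 higher and 1579 lower, and 490 with an absolute log2 difference of at least 1. The groups did not overlap for 4035 genes, against 526 by chance, and 2048 of these were called. The count was 1455 without day 7 array 71, and a fit of only the 8 arrays compared called 856. Higher genes made up 32.1% of the calls as deposited, 59.6% of 890 calls under quantile normalisation, which moved the median over all genes from −0.049 to 0.077, and 42.5% after centring. Camera called 25 lists at the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05.

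From day 1 to day 7 the balance moved from neutrophil to matrix genes. Aspn, the gene of the matrix protein asporin, rose by 7.30 ± 0.77, Col1a1 by 6.19 ± 0.56 and Postn by 5.55 ± 0.67 (SE, n = 4 per group). S100a8 was −7.56 ± 1.00, Arg1 −7.12 ± 0.66 and Retnlg −8.48 ± 0.94, the last with 3 of 4 day 7 values not above the median negative control. Of 41 matrix genes 38 were called higher and 1 lower (39 and 1 adjusted over the list alone; camera adjusted p 9.1e-29), of 13 resident fibroblast genes 11 were called higher and 1 lower, as many adjusted over the list alone (camera adjusted p 1.1e-08), and of 15 neutrophil genes 14 were called lower, as many adjusted over the list alone (camera adjusted p 2.33e-11). Each of these 3 lists had adjusted p = 0.366 with an estimated correlation. Of 23 interferon response genes 10 were called higher (14 adjusted over the list alone; camera adjusted p 2.78e-05, and adjusted p = 0.54 with an estimated correlation). Of 17 endothelial genes 8 were called higher (8, with 1 lower, adjusted over the list alone; camera adjusted p 0.00079, and adjusted p = 0.416 with an estimated correlation). Limma called 0 of 42 oxidative phosphorylation, 0 of 23 citric acid cycle and 0 of 26 fatty acid oxidation genes, and 0 of each also at an unadjusted p under 0.05, but 4 oxidative phosphorylation genes higher without array 31. The camera adjusted p of the oxidative phosphorylation list was 0.0739, but 0.00945 without array 12, 0.0132 without array 31, 0.0235 without array 11 and 0.0388 without array 74. That of the citric acid cycle was 0.104, but 0.0216, 0.0253 and 0.0366 without arrays 12, 31 and 11, and that of fatty acid oxidation 0.153, but 0.0337 without array 12. Each of these 3 energy lists had adjusted p = 0.776 with an estimated correlation over all arrays.

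Limma called 4856 genes between day 1 and day 7 (26.4%), 2515 higher and 2341 lower, and 1206 with an absolute log2 difference of at least 1. The groups did not overlap for 7684 genes, against 526 by chance, and 4508 of these were called. Without array 31, which is in neither group, the count was 9246. Higher genes made up 51.8% of the calls as deposited and 75% under quantile normalisation, which moved the median over all genes from −0.027 to 0.162. Camera called 18 lists at the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05.

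**Figure D3:**
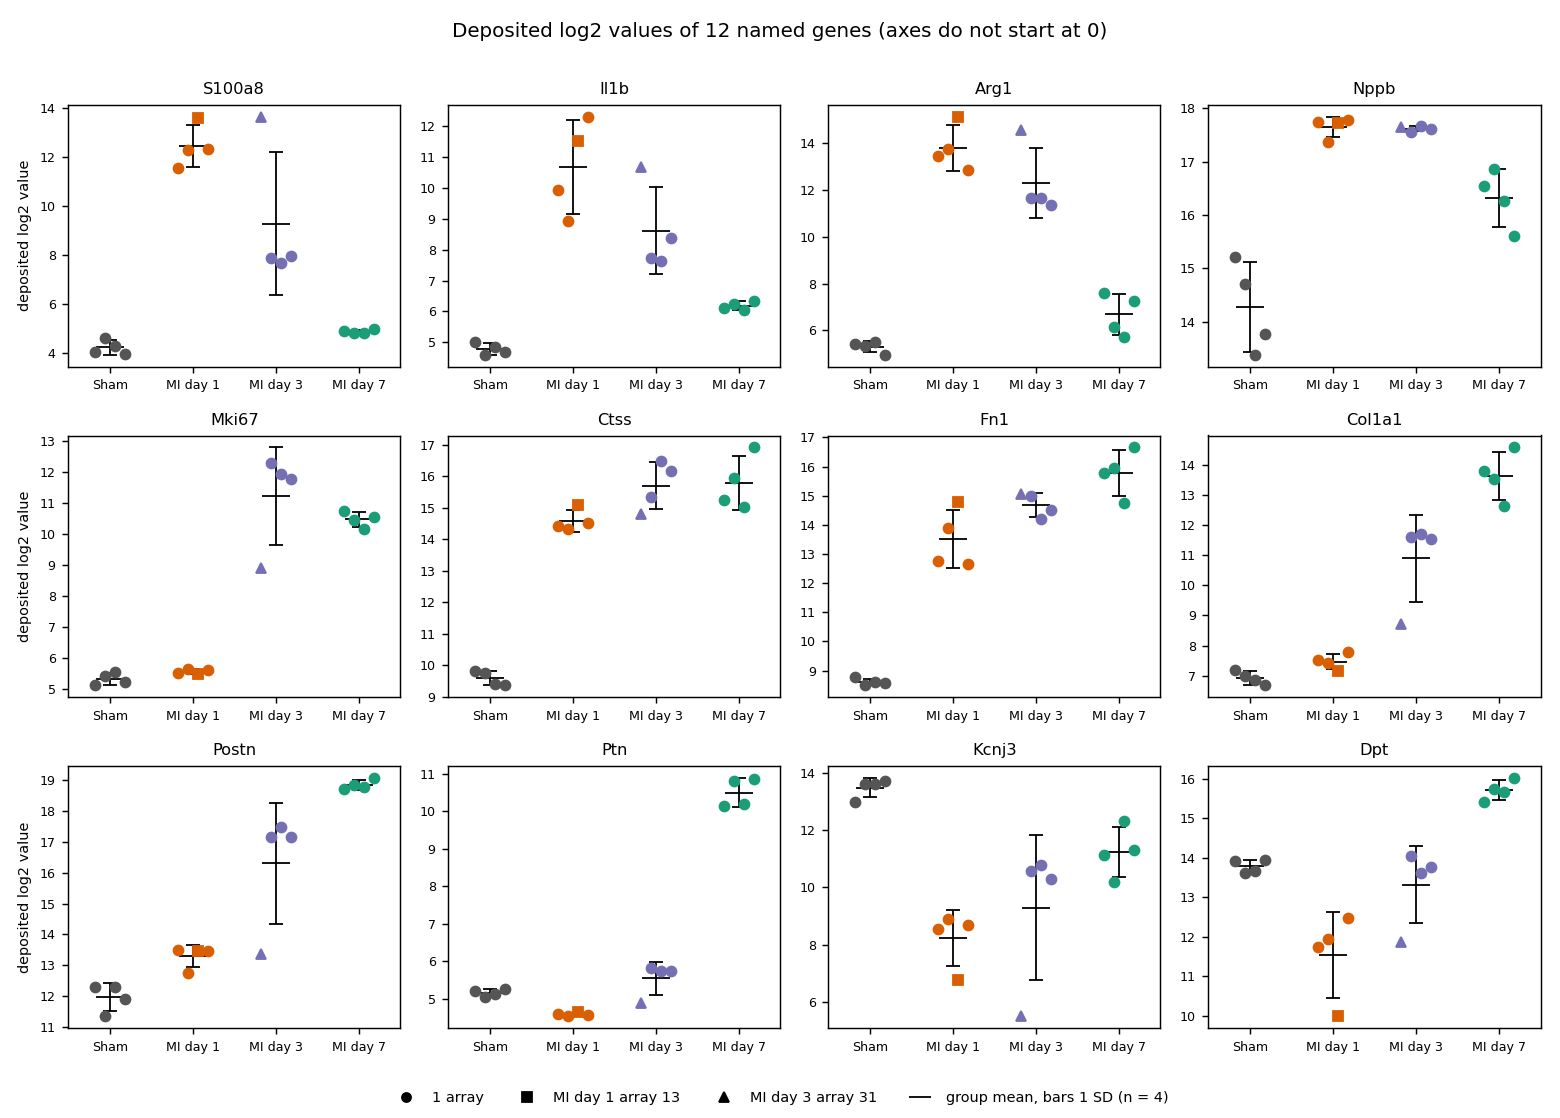
Deposited log2 signal of 12 genes named in the text, 1 point per array in each of the 4 groups, with the group mean and SD (n = 4), on axes that do not start at 0. S100a8 is at 12.45 ± 0.84 on day 1 and 9.28 ± 2.91 on day 3, and Postn is at 18.84 ± 0.16 on day 7 against 11.97 ± 0.45 in sham.

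Over the whole course the F test called 9641 of 18418 genes (52.3%). From day 1 to day 7, 1887 of the 4594 genes higher on day 1 were called lower and 2593 were not called. Of the 4084 lower on day 1, 1265 were called higher. Days 1 and 3 shared 2972 genes called higher and 3088 called lower, against 1080 and 825 for independent calls, at most 2220 and 1439 in simulations with shared sham arrays, and 1957 to 2156 and 1822 to 1870 when each day had its own sham pair. Days 3 and 7 shared 2206 and 1622, against 644 and 369, at most 757 and 714, and 1266 to 1414 and 660 to 933. Days 1 and 7 shared 1501 and 1511, against 684 and 405, at most 745 and 686, and 788 to 876 and 621 to 844. Own-pair counts rest on fewer sham arrays and no independent value was recomputed, so their drop does not give the part due to shared arrays. Correlations of differences were 0.883, 0.81 and 0.587, and 0.856 to 0.873, 0.757 to 0.821 and 0.534 to 0.604 with own pairs.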

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

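The tests of the 3 patterns weighed here were chosen after the patterns had been seen, while the counts over other splits of the arrays were planned. An array is described as standing apart when its gap to the nearest array of its group, divided by the range of the group, passed the limit of Dixon's test for 4 values at the 0.05 level. Over 43 measures and 172 groups, 30 groups had such an array, where 8.6 would be expected by chance. In the day 3 group there were 18, and array 31 was the array apart in all 18.

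Day 3 array 31 stood apart from the other day 3 arrays in muscle and energy genes. Its mean list scores, as log2 differences from sham, given with each list beside those of the other arrays, were −3.25 for atrial genes, −2.62 for sarcomere, −2.29 for calcium handling, −1.45 for ion channels and −1.43 for gap junctions and discs. The scores were −3.26 for fatty acid oxidation, −2.84 for the citric acid cycle and −2.57 for oxidative phosphorylation. It was also apart in matrix genes at 0.88, profibrotic genes at 0.74, resident fibroblast genes at −1.14, cell cycle genes at 1.04, genes of the unfolded protein response at 0.21 and complement genes at −0.15. Its neutrophil score stood apart above the others, at 4.65. Smaller scores also above the others, without passing the limit, were those of acute stress genes at 0.69 (0.49 to 0.64), lymphocyte genes at 0.16 (−0.05 to −0.01), and the 2 red cell, 1 lung and 1 thymus genes. Control separation was 0.743, the median of all values 4.615 (4.18 to 4.22) and the median correlation with the group 0.951.

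The array correlated best with day 1 array 13, at 0.989, and its neutrophil score of 4.65, macrophage score of 1.92 and resident fibroblast score of −1.14 lay within the day 1 ranges of 4.2 to 5.42, 1.81 to 2.13 and −1.43 to −0.71. A day 1 sample under a day 3 label is still argued against by its cell cycle score of 1.04, against 0.14 to 0.22 in the day 1 arrays. Loss of signal alone is argued against because 11 of 15 neutrophil genes lay more than 1 log2 unit above the highest other day 3 array, although the low control separation of arrays 31 and 13 leaves a part of it open. A lower share of cardiomyocytes alone is argued against because 4 of 4 lists of other cell types scored below every other day 3 array while the neutrophil list scored above. A slower course of the response in that mouse, with lower signal on top, may remain, as a hypothesis that was not tested.

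The interferon response score of day 3 array 32, 0.26, lay far below those of arrays 33 and 34, 3.31 and 2.71. Low array quality is argued against by a control separation of 0.825, above the sham range of 0.812 to 0.821. Fewer macrophages are argued against by a macrophage score of 3.03, against 3.28 and 2.99, and an earlier stage by a neutrophil score of 1.61 and a cell cycle score of 2.64. A difference between mice could remain and was not tested.

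Atrial genes scored −2.43 in day 1 array 12, against −1.52 to −1.47 in the other day 1 arrays, and 8 of 12 atrial genes below the ceiling were lowest there. Low array quality is argued against by a control separation of 0.804, the highest of the day 1 arrays. A smaller share of all cardiomyocytes is argued against because 16 sarcomere genes outside the atrial list had a median gap of 0.51 above the other day 1 arrays. More ventricular tissue in that sample cannot be told apart from a difference between mice, since 4 of 6 ventricular genes were highest in array 12, where at least 5 would have favoured it and at most 1 would have argued against it.

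Other arrays stood apart by smaller amounts. Sham 1 scored −0.16 for calcium handling (others 0.04 to 0.08), 0.18 for resident macrophage (−0.06 to −0.05), 0.19 for matrix (−0.09 to −0.05), 0.14 for protease (−0.06 to −0.04) and 0.09 for resident fibroblast genes (−0.04 to −0.02), and its median correlation with its group was 0.996 (0.997 in the others). Sham 4 scored 0.10 for ventricular genes (−0.04 to −0.03). Day 1 array 13 scored −1.37 for calcium handling, −0.95 for circadian clock and −0.58 for Schwann cell and nerve genes. Day 7 array 74 scored 0.66 for neutrophil genes. Of 222 genes named by the rule, 10 had an array apart among the sham arrays, 15 on day 1, 77 on day 3 and 10 on day 7, and array 31 was that array for 76 of the 77.

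Some genes were called in opposite directions on different days, each also called in the direct comparison of those days. From day 1 to day 3, 6 genes went from higher to lower than sham and 11 from lower to higher. From day 3 to day 7 these counts were 6 and 16, and from day 1 to day 7 they were 30 and 116. Camera called the resident fibroblast list lower than sham on days 1 and 3 and higher on day 7, with adjusted p = 0.336, 0.484 and 0.599 with an estimated correlation, and the day 3 call was lost without array 31 (adjusted p 0.158). Its median differences were 1.09 from day 3 to day 7 and 1.92 from day 1 to day 7, where camera gave adjusted p = 0.199 and 0.366 with an estimated correlation. Rows without a gene symbol, not used in the comparisons, were called by limma for 2466 of 14228 on day 1 (1700 higher, 766 lower), 1656 on day 3 (962 higher, 694 lower) and 726 on day 7 (394 higher, 332 lower).

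Of all 35 splits of 8 arrays into groups of 4, only the real grouping called as many genes for days 1, 3 and 7 against sham (8678, 8049 and 4568, highest other 1, 0 and 0). The same held for day 7 against days 3 and 1 (2327 and 4856, 6 and 0). This argues against chance at the lowest possible share, 1 in 35. For the F test 1 of 100 splits, the real grouping, gave 9641 genes and the highest other 566, which also argues against chance. For day 3 against day 1, 4 of 35 splits gave at least 1494 genes, so chance cannot be excluded. The highest other split gave 7394 and exchanged array 12 with array 31, and the next gave 4305 and 2997 by exchanging arrays 11 and 14 with it, which points to array 31 lying near the day 1 arrays. Chance cannot be excluded for the counts of lists called by camera: 6 of 35 splits gave at least 22 lists on day 1 (highest other 23), 6 gave at least 24 on day 3 (25) and 8 gave at least 20 on day 7 (21). Between days, 11 splits gave at least 15 lists for day 3 against day 1 (19), 3 gave at least 25 for day 7 against day 3 (26) and 12 gave at least 18 for day 7 against day 1 (21). For day 3 against day 1 an evenly mixed split also reached 19.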

How the results depend on the processing

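Tests without both arrays of lowest control separation, with control separation as a covariate, without genes near the ceiling, with a block for the lists, and all recounts of overlaps were chosen after the results were seen. Counts of called genes for days 1 and 3 against sham stayed within 1.5 times under every alternative except the minimum difference of 1, and no called value of a named gene turned its direction. The balance of calls against sham, and for day 7 against day 3, did turn under quantile normalisation or centring, as given above. Of 384 values of named genes, 0 to 27 lost their limma call per alternative, the 27 without sham 4. A minimum log2 difference of 1 left 2874, 2847 and 1257 genes for days 1, 3 and 7 against sham, and 426, 490 and 1206 for day 3 against 1, day 7 against 3 and day 7 against 1, because it removes small differences. For the rest the cause was not tested. Day 7 against sham gave 8279 genes with array weights, 7121 with only the 8 arrays compared, 7479 without both low arrays and 7557 with the covariate. Day 3 against day 1 gave 775 under quantile normalisation, 7447 with array weights, 254 with only 8 arrays, 5808 without both low arrays, 3793 with the covariate and 807 to 6544 with 1 array left out, the lowest without array 11 and the highest without array 31. Day 7 against day 3 gave, in that order, 890, 5152, 856, 3802 and 4497, and 1455 (without array 71) to 2882 with 1 array left out. Day 7 against day 1 gave 9602 with array weights, 8165 without both low arrays and 3311 to 9246 with 1 array left out, the highest without array 31. The F test gave 14598 with array weights. Genes shared in direction by days 3 and 7, 3828 in all, were 2497 under quantile normalisation, 6941 with array weights, 6188 without both low arrays and 6251 with the covariate. Those shared by days 1 and 7, 3012 in all, were 1884, 5677, 5029 and 4679 in the same order, 4941 with only 8 arrays, and 2229 to 4571 with 1 array left out, the highest without array 31.

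With an estimated correlation camera called 0 lists in each of the 6 comparisons, and 7, 6, 7, 4, 5 and 5 had an unadjusted p under 0.05, in the order of the comparisons above. Without both low arrays it called 1, 1, 1, 2, 6 and 3 lists, among them the neutrophil list on day 1 (adjusted p 0.0226) and the cell cycle list on days 3 and 7 (adjusted p 0.0404 and 0.0452). With 1 array left out, lists called for day 3 against day 1 ranged from 9 to 20, the lowest without array 31. Replicate numbers do not pair the arrays. By correlation of deviations from the group means, the best match in another group shares the last digit for 3 of 16 arrays, and pairs with the same digit ranged from −0.67 to 0.65, although all 6 pairs of digit 2 were positive (0.08 to 0.65). A block on that digit gave 8142, 7891, 4273, 1321, 2004 and 4367 genes and is a hint only. Of the genes called, 8452, 7709, 4568, 1471, 2191 and 4750 kept their call and direction without both low arrays. Signal over background, lowest in arrays 31 and 13, limits what can be read, and no difference can be read at the ceiling.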

Other observations

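The tests with limma and camera given here were planned, except those without arrays 31 and 13 together, which were chosen after the values were seen, as were the genes named for their opposite course. More clock genes were called lower than higher on each day. Of 15 circadian clock genes 9 were called lower and 2 higher on day 1 (9 and 3 adjusted over the list alone), 8 lower and 1 higher on day 3 (10 and 1 adjusted over the list alone) and 5 lower on day 7 (6 adjusted over the list alone). Dbp, a clock output transcription factor gene, stood at 9.81 ± 0.26 in sham, 6.45 ± 0.51 on day 1 and 6.29 ± 0.51 on day 3 (SD, n = 4), with log2 differences of −3.37 ± 0.27, −3.52 ± 0.27 and −1.17 ± 0.27 (SE) on days 1, 3 and 7. The day 1 clock score was −0.95 in array 13 and −0.65 to −0.64 in the others. The camera adjusted p was 0.00189, 0.000157 and 0.00512, or adjusted p = 0.259, 0.158 and 0.271 with an estimated correlation. The hour of tissue collection is not given in the sources used here. Of 17 glucocorticoid response genes 6 were called higher and 2 lower on day 1 (6 and 3 adjusted over the list alone), with a median of 0.29 that turned to −0.13 under quantile normalisation, 4 and 4 on day 3 and 2 and 3 on day 7, both as adjusted over the list alone (camera adjusted p 0.157, 0.509 and 0.247).

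Genes of the unfolded protein response, which help proteins fold in the endoplasmic reticulum, were higher early. Of 19 such genes 14 were called higher and 2 lower on day 1 (14 and 3 adjusted over the list alone), 12 and 4 on day 3 (13 and 4 adjusted over the list alone), and 2 and 3 on day 7, as adjusted over the list alone, or 2 and 5 after centring. The transcription factor gene Xbp1 rose by 1.84 ± 0.19 on day 1, and Pdia6, a folding enzyme gene, by 1.86 ± 0.19 on day 3, where the list score was 0.21 in array 31 and 0.58 to 0.61 in the others. The camera adjusted p was 0.00121, 0.011 and 0.782, or adjusted p = 0.343, 0.402 and 0.932 with an estimated correlation. From day 3 to day 7, 10 of these genes were called lower (12 adjusted over the list alone; camera adjusted p 4.93e-05, and adjusted p = 0.352 with an estimated correlation). Of 20 complement and coagulation genes 8 were called higher and 4 lower on day 1, as many adjusted over the list alone, 10 and 2 on day 3 (12 and 3 adjusted over the list alone) and 10 and 2 on day 7 (12 and 2 adjusted over the list alone). The complement receptor gene C3ar1 rose by 4.07 ± 0.47 on day 7. Their camera adjusted p was 0.216, 0.167 and 0.00047, the last with adjusted p = 0.316 with an estimated correlation. The day 3 value became 0.0435 without array 31, whose score was −0.15 against 0.68 to 0.85, and 0.0338 without arrays 31 and 13, the latter with adjusted p = 0.276 with an estimated correlation.

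Among the 116 genes called below sham on day 1 and above it on day 7, which were not tested for a shared function, 5 are given here. Col14a1, which encodes a collagen that binds fibrils, had log2 differences of −1.37 on day 1 (adjusted p 0.012) and 4.01 on day 7 (adjusted p 1.1e-05). Dpt was −2.24 and then 1.92, Ccdc80 −1.09 and then 1.78, Antxr1, the gene of a collagen-binding receptor, −0.69 and then 2.73, and Cd34, a marker of resident fibroblasts and vessel cells, −1.79 and then 1.13.

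Single markers of tissues that an atrial dissection could carry had the following mean log2 values. Sftpc, the lung surfactant gene, stood at 3.05 in sham and 3.14, 3.18 and 3.12 on days 1, 3 and 7, and the fat gene Adipoq at 4.40, 4.34, 4.27 and 4.54. Car3, another gene of fat and also of muscle, stood at 6.47, 5.09, 5.49 and 6.48 in the same order, with an SD of 2.49 on day 7 (n = 4). The brown fat gene Ucp1 stood at 3.34 in sham and 3.95 on day 7, with an SD of 1.54 there. The red cell gene Alas2 was at 6.14, 6.22, 5.96 and 6.09, the thymus gene Dntt at 3.48, 3.47, 3.48 and 3.42, and the skeletal muscle genes Myh4 at 4.59, 4.46, 4.36 and 4.49 and Tnnt3 at 5.06, 5.42, 6.19 and 5.82. Upk3b, of the mesothelium, stood at 7.84, 5.62, 6.82 and 7.14. Of the lists for red cells, lung and thymus, 2, 1 and 1 genes were tested, too few for camera. Limma called 0 of these 4 genes on days 1, 3 and 7, with 1 red cell gene higher on day 1 at an unadjusted p under 0.05.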
